A study of Homo sapiens with 141 samples.

How the data were processed

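Expression was measured in 22 human pancreatic cancer cell lines and 3 specimens labelled as normal pancreatic ductal epithelial cells, on 141 Affymetrix arrays. Per the labels, each line was grown with serum in 3 replicate cultures per arm and received vehicle or CI-1040, an inhibitor of the kinase MEK, for 24 h. The titles call the arrays of the vehicle arm untreated. The labels give the dose as 2 mM, a unit that could not be checked. Each specimen has 3 arrays, and the labels do not say whether these came from separate cultures. The title of specimen 3 calls it cancer cells while its cell type tag says normal ductal epithelium; it was grouped by the tag. One CI-1040 group, L3.3, is numbered differently in its titles and descriptions, and the titles were used. RNA had been purified on columns, amplified and biotinylated per the labels. The sources used here name no batch or run date for the arrays.

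The deposited values are linear intensities for 22277 probe sets, made by the submitters with Affymetrix Expression Console, whose version and summary algorithm the sources used here do not give. Each array had been scaled, since its mean intensity after trimming 2% at each end lay between 500.1 and 500.2. Values were raised to a floor of 1 and taken to log2, and no further scaling was applied. Of the probe sets, 19070 carried 1 gene symbol, 1043 carried several and 2164 none; the last 2 kinds were kept out of the gene comparisons. The brightest probe set by mean over the 141 arrays stood for each of the 4304 genes with more than 1. Genes of X inactivation and the Y chromosome, with 31 probe sets, were left out, so that 11939 genes were tested. No filter on dim genes was applied in the main comparisons.

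The median intensity of an array ranged from 102 to 173, and between 26.2% and 37.4% of its values lay below 50. Below the floor lay 0.0359% to 0.655% of the values. The Pearson r of log2 values between arrays of a group, across genes, which are not independent replicates, ranged from 0.940 to 0.974 with a median of 0.968. The median residual SD of a gene was 0.31 on the log2 scale, and 0.20 in the brighter part of the genes, above the middle of their mean levels. The log2 ratio of 3' to 5' probe sets ran from -0.40 to 0.87 for GAPDH and from -0.11 to 2.20 for ACTB, highest in Panc-1 vehicle replicate 1. The number of arrays limits the precision.

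The CI-1040 effect over lines was tested with limma 3.58.1 in R 4.3.3 on 22 differences, each the mean of 3 CI-1040 arrays minus the mean of 3 vehicle arrays of a line. Changes within each line, and the F test of the 21 line-by-treatment terms, came from 1 limma fit of the 141 arrays in 47 groups with 94 residual degrees of freedom. Means of gene lists in each line were tested in a linear model of the list means over the same 47 groups. Lines and normal specimens were compared by limma on the vehicle means of 22 lines and the means of 3 specimens. The tests of genes and lists were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, over all genes or, for the lists within lines, over the 22 lines.

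Before the data were examined, 33 gene lists were written from general knowledge, and all had at least 5 measured genes. They were tested with camera of limma at a preset correlation of 0.01, with adjustment over the 33 lists. The tests with an estimated correlation and with fry served as alternatives. The mean change of a list of 10 transcripts used as readouts of MEK and ERK activity (MAPK output) was tested with 100000 random sign flips of the lines. Correlations between lines, 4 in number, used 18 units: COLO357, L3.3, L3.6pl and L3.6sl were averaged into 1, as were PL45 and Panc-10.05, because these lines are known to share an origin. The relation between changes of MAPK output and proliferation used all replicates. In the other three, vehicle levels came from replicate 1 and changes from replicates 2 and 3. Each had 100000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for preparation and plots.

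The genes named in the text were set by a rule written before the data were examined. Over lines, these were the 12 largest rises and 12 largest falls among genes past the threshold that moved that way in at least 20 lines, and the 10 MAPK output genes. For the differences between lines, they were the 10 genes with the largest F, and for the normal specimens the 12 genes with the largest differences each way. Up to 3 members with the smallest p stood for each list. Any other gene is said to have been chosen after its values were seen.

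The pipeline was tested on simulated data with 200 changed genes among 11939. Noise was drawn independently for each gene, with the same SD in all groups. Correlated genes, noisier lines and deviations shared by a replicate number were thus not simulated. Over lines, 88% of changes of 0.5 and 99% of changes of 1 on the log2 scale were called, with 11 false among 198 calls. Within 1 line, 60% of changes of 1 and 80% of changes of 2 were called. Against the specimens, 76% of differences of 2 and 96% of differences of 4 were called. The alternatives were other scalings, all probe sets of a gene, a mild and a strict filter on dim genes, other intensity floors, other variance priors, blocks for lines or replicate numbers, merged lines, and the omission of replicates, lines or specimens.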

Results

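The 141 arrays comprised 66 of vehicle-treated lines and 66 of CI-1040-treated lines, 3 per line and arm, and 9 of normal ductal epithelial specimens, 3 per specimen. CI-1040 blocks MEK, the kinase that activates ERK, and the series was made to find which transcripts depend on MEK in pancreatic cancer cells. Values below are log2 intensities, and changes are differences of these. The p-values within a line rest on the pooled spread between arrays of all 47 groups, although the replicate SD ranged from 0.156 in HPAF_II to 0.331 in Panc-10.05. Those against the specimens cover only 3 specimens, whose arrays are not said to come from separate cultures.

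The first question was which transcripts changed with CI-1040 across the lines. Among genes that fell in at least 20 lines, transcripts known as readouts of ERK had the largest mean falls. DUSP6, a phosphatase that switches ERK off, fell by 2.64 (SE 0.28, n = 22 lines), which is 6.24-fold, and was lower in 22 of 22 lines. ETV4, an ETS transcription factor, fell by 2.59 (SE 0.26), and its relative ETV5 fell by 2.17 (SE 0.23). FOSL1, an AP-1 subunit stabilised by ERK, fell by 2.20 (SE 0.24), 4.58-fold, in 21 lines. The adjusted p-values in limma were 5.84e-07 for DUSP6, 3.69e-07 for ETV4, 4.89e-07 for ETV5 and 6.24e-07 for FOSL1. The size and rank of ETV4 depended on the intensity floor: with a floor of 64 it fell by 1.19, less than DUSP6 at -2.37, ETV5, FOSL1 at -1.92, DSCC1 at -1.27, SLCO4A1 at -1.24 and CDC45 at -1.20.

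Other large falls included ORC1, DSCC1 and CDC45, which act in DNA replication. ORC1, of the origin recognition complex, fell by 1.44 (SE 0.23), DSCC1 fell by 1.37 (SE 0.19) and CDC45, of the replicative helicase, fell by 1.29 (SE 0.20). BRCA1, a DNA repair gene that peaks in S phase, fell by 1.21 (SE 0.18) and was lower in all 22 lines. The transporter SLCO4A1 fell by 1.24 (SE 0.13) in 22 lines with an adjusted p of 4.89e-07. ACOX2, a peroxisomal oxidase, fell by 1.62 (SE 0.27), the glycolytic enzyme ENO2 by 1.29 (SE 0.23) and the collagen COL13A1 fell by 1.23 (SE 0.22). With a floor of 64 the changes were -0.84 for ACOX2, -0.67 for ORC1, -0.52 for ENO2 and -0.94 for COL13A1, all still past the threshold.

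Among genes that rose in at least 20 lines, the largest mean rise was that of CFB. This gene, complement factor B, rose by 2.07 (SE 0.20), 4.21-fold, in 22 lines, with an adjusted p of 3.69e-07. MUC16, the mucin that carries the tumour marker CA125, rose by 2.00 (SE 0.31) and the chloride channel CLIC3 by 1.97 (SE 0.25), both in 22 lines. TRIM22, an interferon-induced antiviral gene, rose by 1.95 (SE 0.23), IL32 by 1.64 (SE 0.19), RTP4 by 1.53 (SE 0.19) and the death ligand TNFSF10 by 1.52 (SE 0.23), 2.87-fold. The remaining large rises were TNNC1 at 1.72, SLC15A3 at 1.60, ALPP at 1.53, PDZK1IP1 at 1.52 and SELENOP at 1.52. Some of these transcripts were dim: with an intensity floor of 64, the rise of MUC16 came to 1.04, that of TNNC1 to 0.89, that of SLC15A3 to 0.61, that of ALPP to 0.65, that of RTP4 to 0.95 and that of IL32 to 1.06, all still past the threshold.

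Of 11939 genes, 4475 passed the threshold, 2642 higher and 1833 lower with CI-1040. Only 74 rises and 38 falls exceeded 2-fold, and 1494 genes moved one way in at least 20 lines. The share of higher genes among the calls, 59.0%, depended on array scaling: it was 50.8% under quantile normalization and 39.7% with arrays centred on their medians. The median intensity was 145.0 in the CI-1040 arrays and 138.4 in the vehicle arrays (permutation p = 3e-05 over 22 lines), and the share of values below 50 was 30.3% and 31.2% (permutation p = 0.00043). The log2 ratio of 3' to 5' probe sets of GAPDH also differed between the arms, at -0.15 and -0.10 (permutation p = 0.0199), while that of ACTB did not pass (permutation p = 0.395). Within replicate numbers 1, 2 and 3 taken alone, 3028, 3163 and 3354 genes passed.

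Among the 10 MAPK output genes, 9 fell, 0 rose and 1 did not pass, and adjusted over the list alone 9 fell and 1 rose. Besides DUSP6, ETV4 and ETV5, SPRY2 fell by 1.02 (SE 0.16), SPRY4 fell by 1.00 (SE 0.16), EPHA2 fell by 0.87 (SE 0.13), DUSP4 fell by 0.77 (SE 0.13), PHLDA1 fell by 0.68 (SE 0.08) and CCND1, cyclin D1, fell by 0.67 (SE 0.14). SPRY2 and SPRY4 encode inhibitors of receptor signalling that ERK itself induces. EPHA4 was the exception, 0.46 higher (SE 0.19) at a dim vehicle level of 3.46, with an adjusted p of 0.0574 over all genes. It passed without replicate 1 (0.0459) and without 1 of 5 lines, at its lowest without Panc-3.27 (0.0233). With an intensity floor of 64, however, EPHA4 was only 0.11 higher (adjusted p 0.352). The list mean changed by -1.20 (SD 0.57, n = 22 lines) and was lower in 22 of 22 lines, with a sign-flip permutation p of 1e-05, the smallest those flips can give. In camera its adjusted p was 3.78e-08, and adjusted p = 0.0902 with an estimated correlation. Within replicate numbers 1, 2 and 3 the mean change was -1.14, -1.22 and -1.22.

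**Figure D1:**
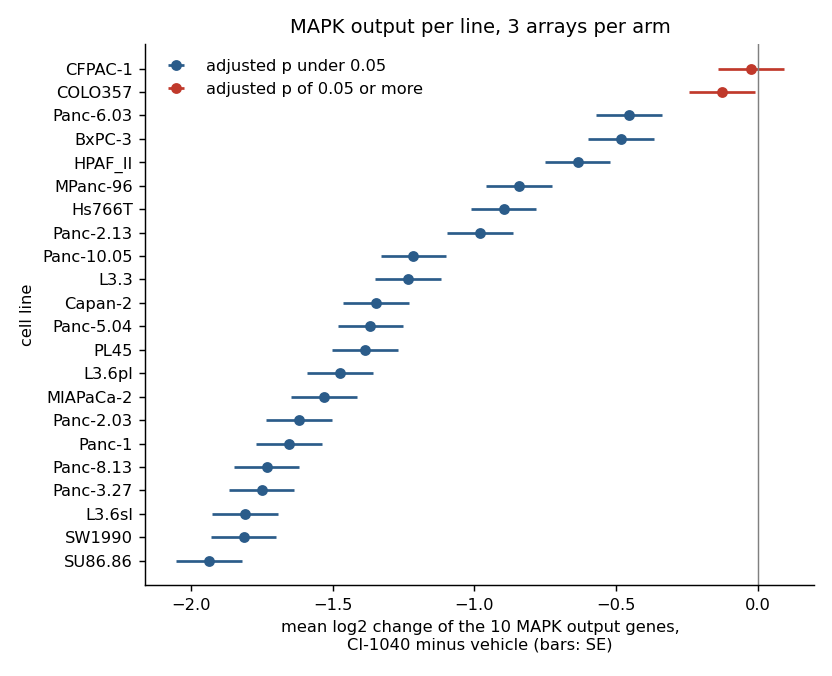
Mean log2 change of the 10 MAPK output genes with CI-1040 in each of the 22 cell lines; points are means of 3 CI-1040 minus 3 vehicle arrays and bars are the SE. SU86.86 lay lowest at -1.94, and COLO357 (-0.13) and CFPAC-1 (-0.02) did not pass the threshold.

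Proliferation lists fell as a whole. All 30 measured genes of G2/M and mitosis fell, 30 also when adjusted over the list alone, among them the spindle checkpoint genes MAD2L1 (fell by 0.90, SE 0.10) and BUB1B (fell by 0.90, SE 0.11) and the topoisomerase TOP2A (fell by 0.83, SE 0.10), each in 22 lines. All 28 genes of G1/S and DNA replication fell, and 28 adjusted over the list alone, with the primase subunit PRIM1 falling most steadily (fell by 0.99, SE 0.11), then RRM1 (fell by 0.74) and RFC5 (fell by 0.73). The list means over 22 lines were -0.78 (SD 0.51) for G2/M and -0.85 (SD 0.60) for G1/S. The camera values were 2.14e-23 and 1.45e-19 after adjustment, and both had adjusted p = 0.118 with an estimated correlation.

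Growth metabolism fell beside them. In MYC targets and ribosome biogenesis 14 of 16 genes fell, 0 rose and 2 did not pass, with 14 falls adjusted over the list alone. NOLC1 fell by 0.55 (SE 0.07), WDR12 by 0.48 (SE 0.07) and FBL, the nucleolar methyltransferase fibrillarin, fell by 0.43 (SE 0.06). In nucleotide and one-carbon metabolism 14 of 15 fell and 15 adjusted over the list alone, with the purine enzyme GART down most steadily (fell by 0.59, SE 0.06). PPAT fell by 0.46 and the serine enzyme SHMT2 fell by 0.45. Their mean changes were -0.40 and -0.45, with camera adjusted p of 6.81e-10 and 7.13e-12; these became adjusted p = 0.118 with an estimated correlation for the first and adjusted p = 0.0949 with an estimated correlation for the second. Glycolysis changed little: 5 of 19 genes fell, HK2 by 0.50 and ENO1 by 0.24, 14 did not pass, and 5 fell adjusted over the list alone. Its mean was -0.14, camera adjusted p 0.0184, and adjusted p = 0.286 with an estimated correlation; the call was also lost when genes below the median level were left out.

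Immediate-early and AP-1 genes were mixed. Of 16, 7 fell, 2 rose and 7 did not pass, while adjusted over the list alone 8 fell and 3 rose. FOSL1 and the stress-response gene IER3 fell (IER3 fell by 1.00, SE 0.16), whereas JUND rose by 0.46 (SE 0.08). The list mean of -0.40 gave a camera adjusted p of 0.032, and adjusted p = 0.478 with an estimated correlation; the call was also lost under quantile normalization, median centring, filters on dim genes and both higher intensity floors. Among invasion and uPA system genes, 10 of 18 fell, 1 rose and 7 did not pass, the same numbers adjusted over the list alone. The integrin ITGA2 fell by 0.76 (SE 0.12) and the protease inhibitor SERPINE2 fell by 0.63, while the matrix metalloprotease MMP7 rose by 0.77 (SE 0.12). The mean of -0.35 had a camera adjusted p of 0.000768, and adjusted p = 0.104 with an estimated correlation, and it too was lost when genes below the median level were left out.

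Interferon and antigen presentation genes rose. In the interferon response list 20 of 22 genes rose, 0 fell and 2 did not pass, and 20 rose adjusted over the list alone. IRF9, of the factor that relays type I interferon signals, rose by 0.70 (SE 0.08), IFI6 by 0.86 (SE 0.11) and the immunoproteasome subunit PSMB9 by 0.95 (SE 0.12). In HLA class I and antigen presentation 10 of 11 rose and 1 did not pass, with 10 rises adjusted over the list alone, among them TAPBP at 0.70 (SE 0.07), PSMB10 at 0.93 (SE 0.11) and HLA-F at 0.54 (SE 0.06). The means were 0.71 (SD 0.41) and 0.52 (SD 0.27) over 22 lines, higher in 21 lines each. Their camera adjusted p-values were 2.71e-10 and 2.65e-07, and each had adjusted p = 0.118 with an estimated correlation. Within replicate numbers 1, 2 and 3 the interferon mean was 0.72, 0.69 and 0.73.

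Lysosomal and epithelial genes rose too. In lysosome and autophagy 17 of 21 genes rose, 1 fell and 3 did not pass, also when adjusted over the list alone. The hydrolase HEXA rose by 0.44 (SE 0.04), the membrane protein LAMP2 by 0.52 (SE 0.06) and the autophagosome gene GABARAPL1 by 0.80 (SE 0.08), each in 22 lines. The list mean was 0.38 (SD 0.15), higher in 22 of 22 lines, with camera adjusted p 1.68e-07 and adjusted p = 0.0902 with an estimated correlation. Of 17 epithelial genes 11 rose, 0 fell and 6 did not pass, with 11 rises adjusted over the list alone. ELF3, an epithelial ETS factor, rose by 1.05 (SE 0.15), SPINT1 by 0.47 and KRT19 by 0.37. The mean of 0.31 (SD 0.24) gave camera adjusted p 0.00739 and adjusted p = 0.298 with an estimated correlation.

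Of the 33 lists, 12 passed in camera, 4 higher and 8 lower, and 0 did with an estimated correlation. With fry, which asks whether the genes of a list move one way on balance and compares no list with other genes, 19 passed. Beyond the 12, these were ERK feedback and EGFR ligands, both lower. Cell cycle brakes and squamous, fibroblast, duct and liver-secreted genes were higher.

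**Figure D2:**
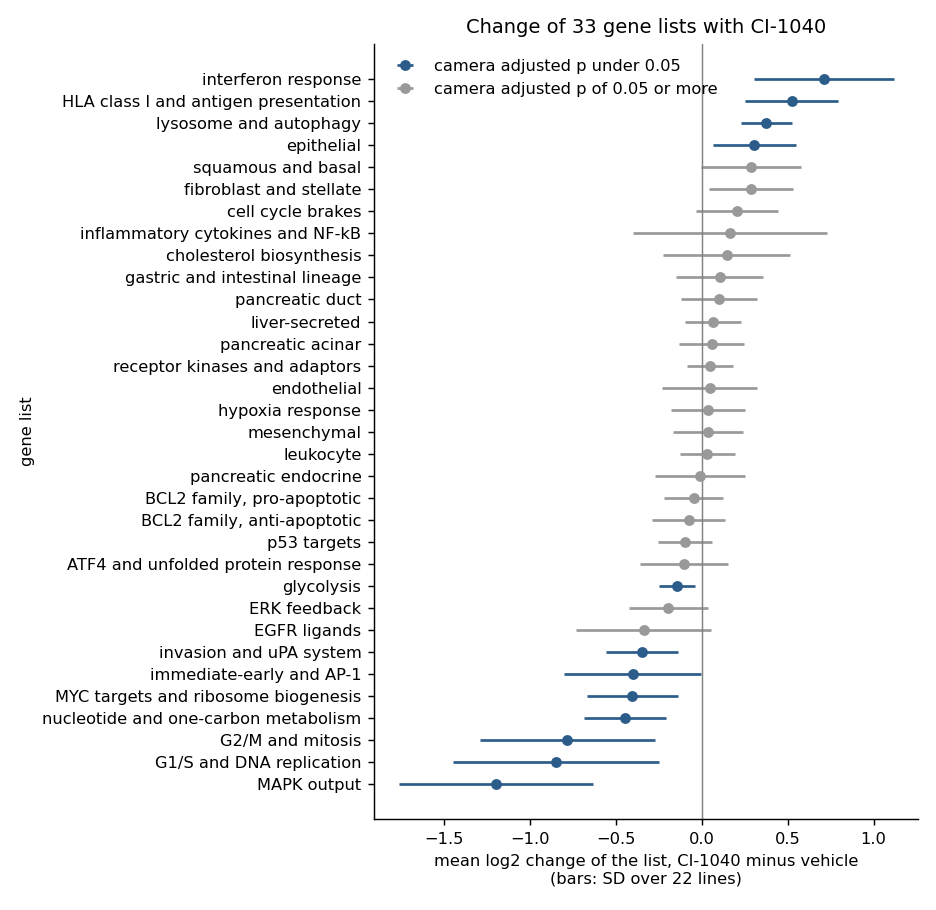
Mean log2 change with CI-1040 of each of the 33 gene lists; points are means over 22 lines, bars the SD over lines, and blue marks the 12 lists past the threshold in camera. MAPK output had the lowest mean, -1.20, and the interferon response the highest, 0.71.

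Several lists tied to drug resistance and cell fate did not pass in camera, though single members did. Of 12 ERK feedback genes 5 fell, 2 rose and 5 did not pass (6 fell and 3 rose adjusted over the list alone): SPRED2, a RAS pathway inhibitor, fell by 0.99 (SE 0.11) in 22 lines and DUSP7 fell by 0.64, whereas DUSP8 rose by 0.69. The mean was -0.19 and the adjusted p 0.178. Of 6 EGFR ligands 3 fell, 1 rose and 2 did not pass, as adjusted over the list alone. HBEGF fell by 1.19 (SE 0.25) and EREG fell by 0.81, while BTC rose by 0.50, with a list mean of -0.34 and an adjusted p of 0.132. Of 18 receptor kinases and adaptors 5 rose, 2 fell and 11 did not pass (5 and 3 adjusted over the list alone). ERBB2 rose by 0.47 (SE 0.07) in 22 lines, ERBB3 by 0.43 (SE 0.07) and the insulin receptor INSR by 0.46. This list had a mean of 0.05, a median of -0.00 and a downward camera test, adjusted p 0.996, and its sign also depended on scaling.

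Cell cycle brakes had 7 rises, 2 falls and 6 not past the threshold among 15 genes (8 and 2 adjusted over the list alone). CDKN1C, the inhibitor p57, rose by 1.26 (SE 0.16), 2.39-fold, in 22 lines, MXI1 by 0.35, and CDKN2D fell by 0.55, a call lost without replicate 2 (adjusted p 0.068). The mean was 0.21 and the adjusted p 0.333. Apoptosis genes moved little. Of 10 pro-apoptotic BCL2 family genes 1 rose and 2 fell, also adjusted over the list alone: BAD rose by 0.26, PMAIP1 fell by 0.48 and BAX fell by 0.18, the last not without replicate 3 (adjusted p 0.101). Their mean of -0.04 and median of 0.06 differed in sign, with an adjusted p of 0.791. Of 5 anti-apoptotic members only BCL2L1 passed (fell by 0.31), 1 adjusted over the list alone, with MCL1 at -0.17 (adjusted p 0.0945, and 0.0393 without Capan-2) and BCL2L2 at 0.08 (adjusted p 0.123). Of 14 p53 targets 2 rose, 5 fell and 7 did not pass, also adjusted over the list alone. ZMAT3 rose by 0.43, PHLDA3 by 0.42 and AEN fell by 0.86, with a list mean of -0.10 and an adjusted p of 0.417.

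Stress, lipid and inflammatory lists did not pass in camera. Of 15 cholesterol biosynthesis genes 4 rose, 0 fell and 11 did not pass (4 adjusted over the list alone), among them MVD at 0.50 (not past without replicate 2, adjusted p 0.0551), LSS at 0.43 and SC5D at 0.31; the mean was 0.14 and the adjusted p 0.381. Of 14 genes of ATF4 and the unfolded protein response 3 rose, 4 fell and 7 did not pass (4 and 4 adjusted over the list alone). TRIB3 fell by 0.72 and ASNS, asparagine synthetase, fell by 0.67, while DNAJB9 rose by 0.26. Mean and median differed in sign, -0.10 and 0.06, with an adjusted p of 0.75. In the hypoxia response 1 of 12 genes rose, 1 fell and 10 did not pass, also adjusted over the list alone. ADM rose by 0.62, VEGFA fell by 0.40 and NDRG1 was 0.25 higher (adjusted p 0.0625, passing without 1 of 4 lines, lowest 0.0202 without COLO357); the mean of 0.04 was opposite in sign to the downward camera test, adjusted p 0.996. Of 18 inflammatory cytokines and NF-kB genes 4 rose, 2 fell and 12 did not pass (5 and 2 adjusted over the list alone). NFKBIA rose by 0.57 (SE 0.07), RELB by 0.30 and LIF fell by 0.74, with a mean of 0.16 and an adjusted p of 0.55.

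Lists of cell lineage did not pass in camera. Of 16 squamous and basal genes 5 rose, 1 fell and 10 did not pass, also adjusted over the list alone: the keratins KRT16 and KRT15 rose by 1.17 and 0.86, and S100A2 fell by 0.42 (list mean 0.29, adjusted p 0.26). Of 15 fibroblast and stellate genes 5 rose and 10 did not pass, also adjusted over the list alone, with LUM at 1.59 (SE 0.36), TAGLN at 0.70 and DCN at 0.27 (mean 0.29, adjusted p 0.214). Of 21 genes of the gastric and intestinal lineage 6 rose, 3 fell and 12 did not pass (7 and 3 adjusted over the list alone). The mucin MUC1 rose by 1.03 (SE 0.15) in 22 lines, ANXA10 fell by 0.90 and FOXA2 fell by 0.72, with a mean of 0.10 and an adjusted p of 0.791. Of 19 mesenchymal genes 1 rose, FN1 by 0.51, and 1 fell, VIM by 0.56, also adjusted over the list alone, and AXL was at -0.32 (adjusted p 0.0537), passing without replicate 2 (0.0498) and without 1 of 3 lines, lowest 0.00576 without MIAPaCa-2. The mean of 0.03 was opposite in sign to the downward camera test, adjusted p 0.996. Of 13 duct genes 2 rose and 11 did not pass, also adjusted over the list alone, KRT7 at 0.22 and KRT19 (mean 0.10, adjusted p 0.67).

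Genes of cell types other than duct served as a background. Of 13 acinar genes 1 rose, SPINK1 by 0.41, and of 13 endocrine genes 1 fell, SCG2 by 0.60, the same counts adjusted over each list alone. Their means were 0.06 and -0.01, the latter with a median of 0.00, and their adjusted p-values 0.996 and 0.791. Of 9 endothelial genes TEK and VWF rose, by 0.32 and 0.26, and 0 adjusted over the list alone (mean 0.05, adjusted p 0.996). Both calls were fragile, at 0.125 and 0.289 for TEK without replicates 1 and 3 (a change of 0.21 without the latter), and 0.124, 0.227 and 0.0574 for VWF without replicates 1, 2 and 3. They were also lost without single lines, with highest adjusted p of 0.057 for TEK (without Panc-2.03) and 0.0758 for VWF (without SU86.86), and with a floor of 64. TIE1 went the other way, at -0.31 (adjusted p 0.0766), and passed without replicate 1 (-0.48, adjusted p 0.0201) or 3 (0.0466) and without L3.6pl (0.0418) or L3.6sl (0.0442). With a floor of 64 TIE1 was at -0.01 (adjusted p 0.413). Of 13 leukocyte genes LYN and CD2 rose, by 0.31 and 0.21, and CORO1A fell by 0.31, with 1 rise adjusted over the list alone. CD2 was lost without replicate 2 (0.0583) or 3 (0.181, a change of 0.13), and CORO1A without replicate 1 (0.167), 2 (0.0691) or 3 (0.0947) and without most single lines (highest 0.0784, without HPAF_II). Both were lost with a floor of 64. Their mean of 0.03 was opposite in sign to the downward camera test, adjusted p 0.996. Of 19 liver-secreted genes CYP2E1 and SERPINA1 rose, by 0.34 and 0.19, and 0 adjusted over the list alone (mean 0.07, adjusted p 0.791). CYP2E1 was lost without replicate 1 (0.0858) or 3 (0.0849), and SERPINA1 without replicate 2 (0.0598) or 3 (0.0748).

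Some genes named for their lists were dim too. With a floor of 64, DUSP8 rose by 0.34, BTC by 0.24, INSR by 0.22, KRT16 by 0.72 and LUM by 0.93. At that floor CDKN2D and FOXA2 each fell by 0.35 and ANXA10 fell by 0.58. All of these were still past the threshold.

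The second question was how far single lines differed. COLO357 and CFPAC-1 had no detected fall of MAPK output: the list mean changed by -0.13 in COLO357 (adjusted p 0.29) and by -0.02 in CFPAC-1 (adjusted p 0.835), each with an SE of 0.12 and 3 arrays per arm. DUSP6 was at 0.00 in CFPAC-1 (adjusted p 0.997), at a vehicle level of 11.92, and ETV4 at -0.22 (adjusted p 0.962). Of the 10 genes only PHLDA1 passed in CFPAC-1, where it fell by 0.71 (adjusted p 7.37e-06), and 0 passed in COLO357. In COLO357, DUSP6 changed by -0.53 (adjusted p 0.641), ETV4 by -0.05 and ETV5 by 0.00. In L3.3, a line derived from COLO357, DUSP6 fell by 3.15 (adjusted p 5.68e-18) from nearly the same vehicle level, 8.38 against 8.33. Tested against the mean of the other 21 lines, COLO357 lay 1.12 higher and CFPAC-1 1.23 higher, with adjusted p of 2.07e-14 and 4.48e-16. The other 20 lines all passed, from -0.45 in Panc-6.03 and -0.48 in BxPC-3 to -1.81 in SW1990 and -1.94 in SU86.86.

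Proliferation genes followed another order. The G2/M list fell in 18 lines. It fell by 1.99 in Panc-5.04. There the log2 3' to 5' ratio of ACTB, a sign of RNA quality, was 0.82, -0.02 and 1.04 on the vehicle arrays. With CI-1040 that ratio was 0.53, -0.02 and 0.33. The G2/M list also fell by 1.52 in CFPAC-1 (adjusted p 5.59e-21), although no fall of MAPK output was detected in CFPAC-1. MAD2L1 fell by 1.15 and TOP2A fell by 1.38 in that line. SU86.86, with the largest fall of MAPK output, had a G2/M change of -0.09 (adjusted p 0.481), and SW1990 had -0.24 (adjusted p 0.0609). G1/S genes fell in 19 lines, by 1.94 in PL45 but by 0.31 in CFPAC-1 (adjusted p 0.00109). COLO357 had 0.13 (adjusted p 0.19), and its G2/M list fell by 0.40 (adjusted p 0.00161). The interferon list rose in 20 lines, by 1.56 in Panc-3.27, 1.39 in Panc-2.03 and 1.11 in Hs766T. It fell in Panc-2.13 by 0.19 (adjusted p 0.0119), and COLO357 was at 0.14 (adjusted p 0.0503).

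The lysosome list rose in 21 lines and HLA class I in 21. Inflammatory genes went both ways, higher in 10 lines and lower in 3, from -1.28 in L3.6sl to 1.34 in BxPC-3. Cholesterol genes rose in 15 lines and fell in 2, from -0.88 in Capan-2 to 0.93 in MPanc-96. Squamous genes rose in 12 lines and fell in 0, as did fibroblast and stellate genes in 11. Invasion genes fell in 16 lines, p53 targets fell in 9 and rose in 2, and glycolysis genes fell in 6.

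The number of genes past the threshold had a median of 1274.5 over lines. It was lowest in COLO357, with 55 genes, 26 higher and 29 lower, and highest in MIAPaCa-2, with 2962, 1527 higher and 1435 lower. Panc-10.05 had 2752, a count that takes its arrays as labelled although its CI-1040 profile lay nearly as close to the vehicle profile of the related PL45 (r = 0.781 across genes) as to its own (r = 0.802). Panc-2.03 had 2648, L3.6pl 420 and CFPAC-1 467. Because the spread is pooled over 47 groups, noisier lines can get more calls. The replicate SD was 0.312 in MIAPaCa-2 and 0.331 in Panc-10.05, though 0.192 in Panc-2.03. The counts of all lines also depend on the arrays at hand: without replicate 1 the median was 799.5, without replicate 2 it was 1236.5, and without replicate 3 it was 600.5. COLO357 had 20 genes without replicate 1 and 16 without replicate 3, and CFPAC-1 had 197 and 204.

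**Figure D3:**
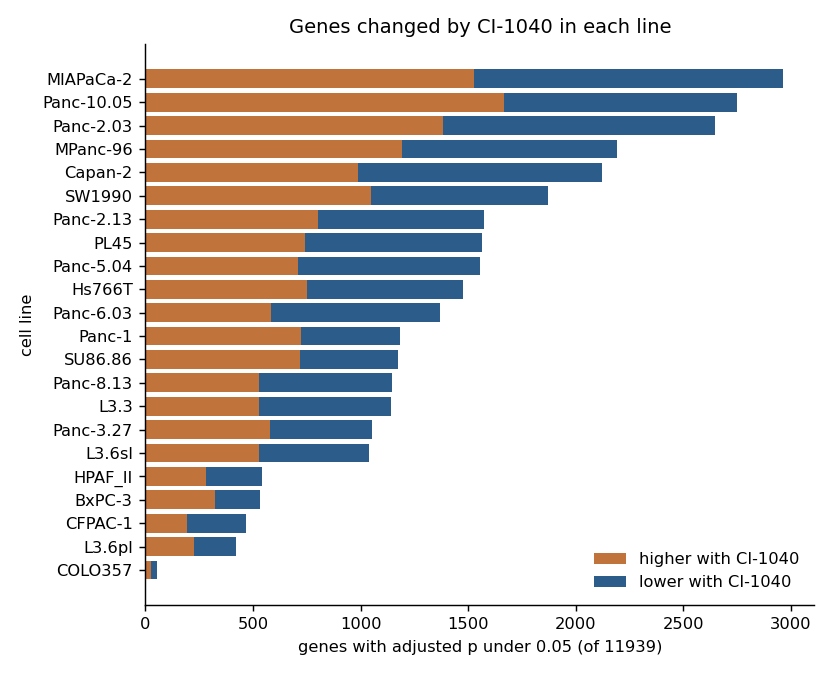
Number of genes past the threshold with CI-1040 in each cell line, of 11939 tested, as bars stacked from higher and lower genes. MIAPaCa-2 had 2962 genes and COLO357 had 55.

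Differences between lines were tested directly with the 21 line-by-treatment terms. CCL20, a chemokine, had the largest F, 56.7, though with a floor of 16 WNT11 led at 322 against 96.8, and with a floor of 64 LUM at 214 against 92.5. CCL20 rose by 5.40 in MPanc-96 and fell by 5.87 in L3.6sl (SE 0.30, 3 arrays per arm), with 5 lines higher and 3 lower. EGR1, an immediate-early factor, fell by 4.99 in MIAPaCa-2 and rose by 1.26 in BxPC-3 (SE 0.20), with 15 lines lower and 2 higher, F 50.1. The chemokine CXCL3 (F 48.5) rose by 2.64 in Panc-8.13 and fell by 2.39 in L3.6sl. TNFSF10 (F 46.6) rose in 20 lines, by 3.64 in MIAPaCa-2, and fell in COLO357 by 0.88. IER3 (F 40.2) fell in 18 lines, by 3.51 in L3.6sl.

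The other five by F were WNT11, PTGES, AQP3, ASS1 and LUM. WNT11, a secreted WNT ligand, rose in 4 lines and by 4.78 in L3.6pl, F 53.3. The prostaglandin synthase PTGES (F 41.3) rose in 12 lines and fell in 4, from -1.90 in L3.3 to 2.07 in Hs766T. The water channel AQP3 (F 38.5) rose in 13 lines, by 3.83 in Panc-2.03, and fell in 1. ASS1, of arginine synthesis, rose in 19 lines and fell in 0, by 2.80 in Panc-2.03, F 37.4. LUM, the matrix protein lumican, rose in 12 lines, F 46.0, but its BxPC-3 vehicle arrays lay at the intensity floor, so that no fold is given for that line.

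In all, 4675 genes, 39.2% of those tested, differed between lines, and 2636 of these also passed over the 22 lines. Without replicate 1 the count of differing genes was 2643, without replicate 2 it was 4244, and without replicate 3 it was 2225.

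Relations between lines were computed for 4 pairs of measures over 18 units, and none passed. The change of MAPK output and that of proliferation gave a Pearson r of -0.0231 (permutation p = 0.927) and a Spearman rho of -0.106 (permutation p = 0.674). The vehicle level of MAPK output and its change gave r = 0.136 (permutation p = 0.591) and rho = -0.0114 (permutation p = 0.967). The vehicle level of epithelial minus mesenchymal genes gave r = -0.0503 with the MAPK output change (permutation p = 0.844; rho = -0.129, permutation p = 0.61). With the proliferation change it gave r = 0.107 (permutation p = 0.669; rho = 0.0485, permutation p = 0.85). All 4 adjusted values were 0.927. Without the 2 units farthest from the median on the x axis, r was 0.158, -0.0835, 0.121 and 0.0508 in that order.

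The last comparison set the 22 vehicle-treated lines against the 3 normal specimens, as a background for the treated lines. NMU, neuromedin U, was higher in lines by 7.57 (SE 1.04), at 9.82 ± 1.86 (SD, n = 22) against 2.26 ± 0.27 (SD, n = 3). PITX1, a homeobox factor of limb development, was higher by 6.96 (SE 0.52) and the serpin SERPINB5 by 6.89 (SE 1.48), with adjusted p of 2.12e-10 and 0.00147 in limma. Next, among genes with at least 20 lines above all 3 specimens, came TNNT1 at 5.34 and PPARG at 5.14. A run of mitotic and replication genes followed: ASPM at 5.13, HELLS, CDC20, NDC80 at 5.03, NCAPH at 5.02, DSCC1 at 4.98 and KIFC1 at 4.89. Several of these lay near background in the specimens. With a floor of 64, SERPINB5 differed by 3.70, PPARG by 3.08, HELLS by 2.28, NCAPH by 2.78, DSCC1 by 2.79 and KIFC1 by 3.14.

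The largest differences the other way were those of OLFM4, CCL2 and CRP. OLFM4, a stem cell marker of the gut, differed by -10.10 (SE 0.84), the chemokine CCL2 by -9.69 (SE 1.51), the acute-phase protein CRP by -8.89 (SE 0.43) and insulin, INS, by -8.31 (SE 0.62). The regenerating proteins followed, REG1A at -8.77 (SE 0.73), REG3A at -8.26 and REG1B at -8.07, then SERPINB7 at -7.96, SERPINA3 at -7.71, PPBP at -7.58, UGT2A3 at -7.43 and DUOX2 at -7.42. Since most of these lay near background in one of the groups, their size and order depended on the intensity floor. With a floor of 64, NMU differed by 3.96, less than CDC20 at 4.34 and ASPM at 4.05, and PITX1 by 2.39. OLFM4 differed by -7.11, a smaller difference than those of REG1A at -7.51 and REG3A at -7.50. CRP differed by -6.21, INS by -5.07 and UGT2A3 by -3.92. All of these passed, whereas TNNT1 at 1.93 no longer passed (adjusted p 0.125).

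Of 11939 genes, 2063 passed, 1132 higher and 931 lower in lines, and the median difference of all genes was 0.13. The count was 1142 without specimen 1, 1308 without specimen 2 and 1209 without specimen 3.

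Proliferation genes were higher in lines. All 30 genes of the G2/M list were higher in lines, 30 also adjusted over the list alone: UBE2C by 12.1-fold, HMMR by 4.55 on the log2 scale and MAD2L1 by 3.40. Of 28 G1/S genes 27 were higher and 1 did not pass (28 adjusted over the list alone), RRM2 by 3.46, POLE2 by 3.41 and TYMS, the target of fluorouracil, by 3.28. The G2/M level was 10.59 ± 0.38 (SD, n = 22) in vehicle, 9.81 ± 0.78 with CI-1040 and 6.68 ± 0.85 (SD, n = 3) in the specimens. The log2 3' to 5' ratio of ACTB, a sign of RNA quality, averaged 0.35 on the specimen arrays and 0.19 on the vehicle arrays. It lay between 0.56 and 0.99 in specimen 1, whose G2/M level of 5.72 was the lowest, and both proliferation lists still passed in camera without that specimen. Camera gave adjusted p of 3.6e-51 for G2/M and 1.7e-30 for G1/S, and these calls held at 0.00388 and 0.00682 with an estimated correlation. Of 16 MYC and ribosome genes 10 were higher, 0 lower and 6 not past (12 adjusted over the list alone), FBL by 1.83, WDR12 by 1.46 and NOLC1 by 1.42, with adjusted p 5.6e-06 and adjusted p = 0.0618 with an estimated correlation. Of 15 nucleotide genes 9 were higher and 6 not past (9 adjusted over the list alone), PAICS by 1.97, PPAT by 1.78 and ATIC by 2.83-fold, with adjusted p 6.83e-06 and adjusted p = 0.0618 with an estimated correlation.

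Genes of differentiated pancreas were higher in the specimens. Of 13 acinar genes 10 were lower in lines and 3 did not pass (11 adjusted over the list alone). The trypsin inhibitor SPINK1 differed by -7.25 (SE 0.58) and the zymogen granule protein GP2 by -4.42. Of 13 endocrine genes 7 were lower, 1 higher and 5 not past (8 and 2 adjusted over the list alone), INS, glucagon GCG at -7.14 (SE 0.46) and somatostatin SST at -4.94. Of 13 duct genes 6 were lower, 0 higher and 7 not past (7 adjusted over the list alone), the secretin receptor SCTR at -4.57 (SE 0.46), CFTR at -1.88 (SE 0.35) and SPP1 at -7.18 (SE 1.53). The list means differed by -4.30, -2.46 and -2.39, with camera adjusted p of 3.88e-16, 3.58e-06 and 1.46e-05. These 3 calls held with an estimated correlation, at 0.00388, 0.0108 and 0.0361, but filters on dim genes ended the endocrine and duct calls. Several of these genes lay near background in lines, and with a floor of 64 GCG differed by -4.86, SST by -3.47, SCTR by -3.25 and CFTR by -0.45, all still past the threshold.

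Stromal and inflammatory genes were higher in the specimens too. Of 15 fibroblast and stellate genes 11 were lower in lines, 0 higher and 4 not past (12 and 1 adjusted over the list alone), among them COL1A2 at -5.51 (SE 0.73), DCN at -3.51 (SE 0.28) and BGN at -2.53. Of 18 inflammatory genes 10 were lower and 8 not past (14 adjusted over the list alone), CCL2, CXCL2 at -3.08 (not past without specimen 1, adjusted p 0.0647) and TNFAIP3 at -2.78. Of 21 lysosomal genes 6 were lower and 15 not past (10 lower and 1 higher adjusted over the list alone), CTSS at -4.01, WIPI1 at -2.10 and LAMP2 at -1.91. The means were -3.13, -2.92 and -1.02, with camera adjusted p of 1.59e-09, 3.6e-08 and 1.46e-05, and the calls held at 0.00861, 0.0399 and 0.00861 with an estimated correlation.

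The MAPK output list did not differ between lines and specimens in camera, with a mean difference of 0.55 (adjusted p 0.485) and 1 of 10 genes past the threshold, also adjusted over the list alone. That gene was ETV4, higher in vehicle-treated lines by 2.38 (SE 0.49, adjusted p 0.00111), or by 1.24 with a floor of 64. With the CI-1040 arms in place of the vehicle arms, the ETV4 difference was -0.21. The list level was 8.93 ± 0.52 in vehicle, 7.73 ± 0.69 with CI-1040 and 8.38 ± 0.14 in the specimens. The interferon list had 0 of 22 genes past the threshold in limma, 0 adjusted over the list alone, with a mean difference of 0.41 (adjusted p 0.824).

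A further 12 lists were lower in lines in camera, with calls that were lost with an estimated correlation. Mesenchymal genes had 8 of 19 lower and 11 not past (9 lower and 2 higher adjusted over the list alone), COL5A1 at -4.95 and FAP at -4.05 (-2.37 with a floor of 64), with adjusted p 5.85e-05 and adjusted p = 0.0618 with an estimated correlation. Invasion genes had 6 of 18 lower (6 adjusted over the list alone), the metalloproteases MMP10 at -5.99, MMP7 at -5.05 and MMP3 at -4.09, with adjusted p 8.45e-05 and adjusted p = 0.0846 with an estimated correlation. Liver-secreted genes had 6 of 19 lower and 2 higher, also adjusted over the list alone, with albumin, ALB, at -7.22 (SE 0.39) and FGG at -6.57, or -5.77 and -4.73 with a floor of 64. Their adjusted p was 0.00123, and adjusted p = 0.191 with an estimated correlation. Hypoxia genes had 3 of 12 lower (4 adjusted over the list alone), ANGPTL4 at -6.64 (SE 0.94), LOX at -3.35 and ADM at -1.72 (not past without specimen 1, 0.287, or 3, 0.147, nor without replicate 1, 0.0722, or 3, 0.0658, nor with a floor of 64, 0.0539), with adjusted p 0.00339 and adjusted p = 0.178 with an estimated correlation. Immediate-early genes had 4 of 16 lower, also adjusted over the list alone, ATF3 at -2.38 (0.0626 without specimen 1), EGR3 at -1.74 and JUNB at -1.35 (0.0704, 0.137 and 0.144 without specimen 1, 2 and 3), with adjusted p 0.0117 and adjusted p = 0.191 with an estimated correlation. HLA class I genes had 2 of 11 lower (5 adjusted over the list alone), TAPBP at -1.45 (0.0628 without specimen 3) and HLA-E at -0.95 (0.212, 0.107 and 0.114 without specimen 1, 2 and 3, 0.0507 without replicate 1), with adjusted p 0.0117 and adjusted p = 0.329 with an estimated correlation.

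The other six of these lists had adjusted p-values nearer the threshold. Genes of ATF4 and the unfolded protein response had 3 of 14 lower (4 adjusted over the list alone), VLDLR at -2.86 and DNAJB9 at -1.94, with adjusted p 0.0154 and adjusted p = 0.329 with an estimated correlation; the call was lost without specimen 1 (0.0692) or 3 (0.0869). Receptor kinases had 4 of 18 lower (4 lower and 2 higher adjusted over the list alone), PDGFRA at -4.11 and PDGFRB at -2.80 (-1.54 and -1.23 with a floor of 64), with adjusted p 0.0219 and adjusted p = 0.128 with an estimated correlation, and 0.0537 without specimen 3. Epithelial genes had 0 of 17 past the limma threshold, 0 adjusted over the list alone, ELF3 at -1.74 (adjusted p 0.0931); the list had adjusted p 0.0312 and adjusted p = 0.6 with an estimated correlation. Of 14 p53 targets 2 were lower (4 adjusted over the list alone), CDKN1A, the inhibitor p21, at -3.17 (SE 0.65) and GDF15 at -2.98, which did not pass without specimen 1 (0.153), 2 (0.0501) or 3 (0.0815). Of 15 cell cycle brakes 4 were lower (5 lower and 1 higher adjusted over the list alone), CDKN1A again, CDKN1C at -2.68 (0.0889 without specimen 1) and KLF6 at -2.10. Of 21 gastric and intestinal genes 2 were lower (1 adjusted over the list alone), MUC6 at -2.82 (-1.24 with a floor of 64, 0.0816 and 0.126 without specimen 1 and 2) and PIGR at -1.64 (-0.71 without specimen 3, adjusted p 0.506, 0.0516 without specimen 1, 0.0576 without replicate 1). These 3 lists had adjusted p of 0.0452, 0.0494 and 0.0494. The calls were lost, at adjusted p = 0.349 with an estimated correlation for p53 targets, adjusted p = 0.186 with an estimated correlation for brakes and adjusted p = 0.528 with an estimated correlation for gastric genes. They were also lost for p53 targets without specimen 1 (0.053) or 2 (0.0731) and replicate 2 (0.0539), for brakes without specimen 1 (0.125) or 3 (0.0722) and replicate 1 (0.0752), and for gastric genes without specimen 2 (0.0653) or 3 (0.0823) and replicate 2 (0.0539).

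Lists that did not pass included ERK feedback, with 2 of 12 genes lower, also adjusted over the list alone, DUSP1 among them (adjusted p 0.00226 in limma), and a list adjusted p of 0.222. EGFR ligands had EGF lower at -2.83 (-1.69 with a floor of 64), 1 of 6 also adjusted over the list alone; their mean of 0.01 was opposite in sign to the median of -0.17 and the camera test (adjusted p 0.609). Pro-apoptotic BCL2 genes had 0 of 10 past the threshold in limma, 0 adjusted over the list alone (mean -0.30, median 0.01, adjusted p 0.609). Anti-apoptotic ones had 2 of 5 lower, also adjusted over the list alone, BCL2A1 at -3.66 (-2.34 with a floor of 64, 0.0763, 0.0768 and 0.106 without specimen 1, 2 and 3) and MCL1 at -0.93, with a list adjusted p of 0.0802. Glycolysis had PFKFB3 at -2.44, PFKFB4 at -1.13 (-0.08 with a floor of 64) and PFKM at 0.97, the 3 of 19 past the threshold over all genes and adjusted over the list alone (adjusted p 0.33). Without specimen 1, PFKFB4 differed by -0.59 (adjusted p 0.172) and PFKM gave an adjusted p of 0.137, and PFKM did not pass without specimen 2 (0.151) or 3 (0.0801). Without replicate 2 PFKM gave 0.0567, and without replicate 3 PFKFB4 differed by -0.73 (adjusted p 0.114). Of 16 squamous genes SERPINB4 passed at -4.59, also adjusted over the list alone, but not without specimen 1 (0.0907) or 3 (0.0861) (mean 0.42, adjusted p 0.758). Cholesterol genes (0 of 15; adjusted p 0.339), endothelial genes (0 of 9; adjusted p 0.485) and leukocyte genes (0 of 13; adjusted p 0.971) had none past the threshold, nor adjusted over the list alone. The leukocyte mean was 0.11 and its median -0.03, with a downward test.

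**Figure D4:**
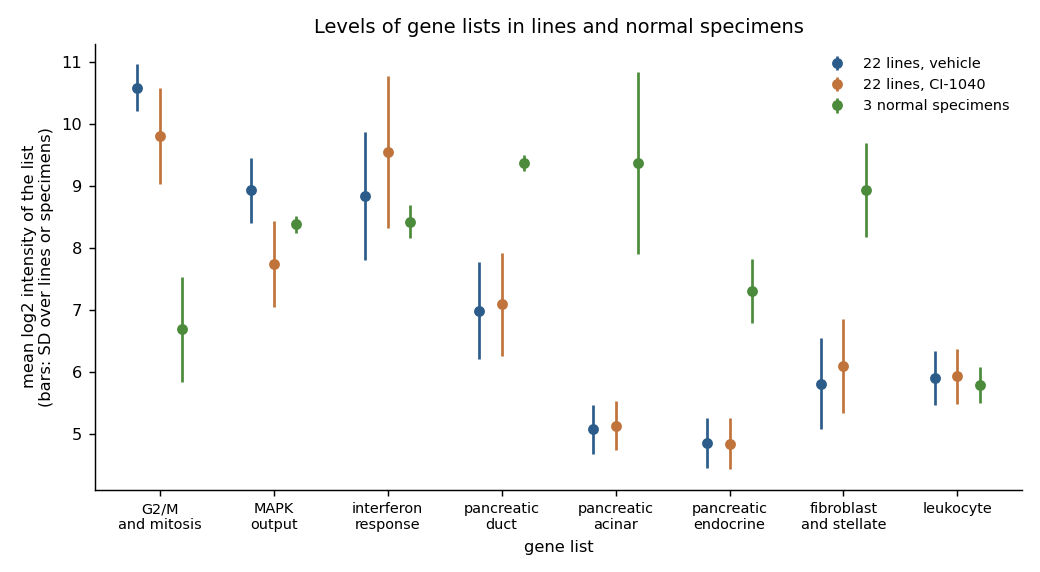
Mean log2 intensity of gene lists in vehicle-treated lines, CI-1040-treated lines and normal specimens; points are means over 22 lines or 3 specimens and bars the SD. The G2/M list averaged 10.59 in vehicle and 6.68 in the specimens, and the acinar list 5.07 and 9.37.

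Of the 33 lists, 22 passed in camera, 4 higher and 18 lower in lines, and 8 of these held with an estimated correlation: G2/M, G1/S, acinar, endocrine, duct, fibroblast, inflammatory and lysosomal genes.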

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

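The tests of noise between arrays, of the interferon rise and of the normal specimens were chosen only after those results were seen; the tests of other lines' arrays, of an ineffective inhibitor and of other splits were set beforehand, except that the SD in the inhibitor test was put on a common sign of the splits after its values were seen.

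MAPK output changed least in CFPAC-1 and COLO357, at the end of a graded series. Relative to the mean of the other 21 lines, the change of this list differed in 16 lines (SE 0.12). It was higher in CFPAC-1 by 1.23, COLO357 by 1.12, Panc-6.03 by 0.78, BxPC-3 by 0.75, HPAF_II by 0.59, MPanc-96 by 0.37 and Hs766T by 0.31. It was lower in SU86.86 at -0.78, SW1990 at -0.65, L3.6sl at -0.64, Panc-3.27 at -0.58, Panc-8.13 at -0.56, Panc-1 at -0.48, Panc-2.03 at -0.44, MIAPaCa-2 at -0.35 and L3.6pl at -0.29.

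The lack of a detected fall in COLO357 and CFPAC-1 was weighed against 3 technical explanations, of which arrays of another line were argued against: the CI-1040 profiles correlated with the own vehicle profile more than with any other line, by 0.278 in COLO357 (0.947 against 0.669 with L3.3) and 0.615 in CFPAC-1. Noise between arrays was argued against only for a fall as large as the median of the other 20 lines, -1.38, since the lowest value within either 95% interval was -0.36; a smaller fall stays open, and the gap to the next line, Panc-6.03 at -0.45, was not tested. An ineffective inhibitor was not settled in CFPAC-1. Its change correlated over genes with the mean change of the other lines at r = 0.431. The highest of the other 9 splits of its arrays gave 0.310, with an SD of 0.0337 over those splits. Each of those splits mixes the arms and keeps part of their contrast, so that SD is no measure of spread without a drug effect. The SD also took its common sign after its values were seen, and 10 splits are too few for a share under 0.05. What r shows is a difference between the arms that was shared with the other lines, whatever its cause. An ineffective inhibitor cannot be told apart in COLO357 either, where r = 0.104 exceeded the highest other split (0.0877) by less than their SD of 0.0306. Part of a response may be present, as the G2/M list fell by 1.52 in CFPAC-1 and by 0.40 in COLO357, and PHLDA1 of the MAPK list fell by 0.71 in CFPAC-1 (adjusted p 7.37e-06; chosen after its values were seen), but a weaker dose or unequal cultures could give this too, and insensitivity of either line was not tested.

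The rise of the interferon response list may be a response to MEK inhibition. Array scaling was argued against, since the lowest median change over the 3 scalings was 0.67. Slower cycling was left undecided: over 18 units the interferon change and the cell cycle change gave r = 0.06 (permutation p = 0.814, adjusted 0.814; rho = -0.108, permutation p = 0.668), -0.0784 without the 2 farthest units, with a 95% interval of -0.419 to 0.512. The depth of the MAPK output fall was undecided likewise, at r = -0.338 (permutation p = 0.172, adjusted 0.343 over both relations; rho = -0.218, permutation p = 0.384), -0.249 without the 2 farthest units and an interval of -0.695 to 0.153. An effect of the drug outside MEK stays open and was not tested.

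The acinar and endocrine transcripts in the normal specimens may come from cells of other pancreatic types in them, which was left undecided. The acinar mean ranged over the 3 specimens by 2.93 and the endocrine mean by 1.04, against 0.26 for the duct list. However, the G2/M list ranged by 1.60, more than the endocrine list. The fibroblast list ranged by 1.40, but it marks cells other than duct, so its range cannot count against mixed specimens. The endothelial list ranged by 1.29, also more than the endocrine list. Its levels of 4.06, 4.51 and 3.21 were dim, and its mean of 3.92 was no higher than the 4.55 in vehicle-treated lines. Such a range can thus arise in dim genes without a sign of the cells they mark. The acinar genes differed among themselves, with an SD over specimens of 1.15 for GP2 but 0.245 for SPINK1 and 0.195 for REG1A. SPINK1 and REG1A lay near the top of the intensity scale. INS lay at 11.28, 12.06 and 9.92 in specimens 1, 2 and 3, and GCG at 11.04, 12.23 and 9.32. A higher background on the specimen arrays was argued against, since leukocyte and endothelial genes had a median difference of 0.11, lines minus specimens, where background would lower it. Loss of these programmes in the cancer lines was not tested. It would bear on the lines, not on why specimens labelled ductal hold these transcripts.

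The 10 genes with the largest F of the difference between lines were CCL20 (56.7), WNT11 (53.3), EGR1 (50.1), CXCL3 (48.5), TNFSF10 (46.6), LUM (46.0), PTGES (41.3), IER3 (40.2), AQP3 (38.5) and ASS1 (37.4). Outside the gene comparisons, 708 of 3151 probe sets with no gene or several genes passed the threshold with CI-1040 over 22 lines, 427 higher and 281 lower.

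Chance was argued against for all 4 counts of genes as totals, since each was reached by only 1 of 100 splits, the real one. That is the smallest share such splits can give, and it says nothing about single genes or single lines. Splits drawn within lines mostly mix the arms, so part of the real effect stays in their spread. Over lines the real count was 4475 and the highest with the arms exchanged was 1. Per line the medians were 1274.5 and 15, and for genes differing between lines the counts were 4675 and 986. Against the specimens the real count was 2063 and the highest other 40, in a choice of Panc-6.03 with 2 specimens.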

How the results depend on the processing

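The alternatives were chosen before the data were examined, except the intensity floors of 16 and 64 and the omission of Panc-1 vehicle replicate 1, which were chosen after seeing the data.

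The count over lines stayed within 1.5 times in all alternatives, from 3898 to 4561 in those leaving out a replicate or line, and MAPK output stayed between -1.25 and -1.16 there. Of 4535 values of named genes with CI-1040, 4402 kept direction and call, 76 lost and 56 gained a call, and 1 (INS, without a call) moved. For lists with CI-1040, 383 of 452 were kept, 20 lost, 7 gained and 42 uncalled ones moved; against the specimens 458 of 518 were kept, 49 lost and 11 moved. Of 2039 values of named genes against the specimens, 1944 were kept, 64 lost, 30 gained and 1 reversed: ETV4, -0.21 with CI-1040 arms in place of vehicle.

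Changes per line had a median of 736.5 with each line fitted on its own 6 arrays. Leaving out a replicate number gave 600.5 (without replicate 3) to 1236.5 (without replicate 2), and leaving out only Panc-1 vehicle replicate 1 gave 1350.5. Genes differing between lines ranged from 2225 (without replicate 3) to 4777 (without Panc-1 vehicle replicate 1) on leaving out arrays. Over all alternatives they reached 5833 with a floor of 64. Leaving out any replicate number lowered both counts, and the omission of replicate 2 lowered them least, to 1236.5 and 4244. Leaving out only the array Panc-1 vehicle replicate 1 raised both, so fewer arrays need not lower such counts. The causes were not tested. The specimen comparison gave 1327 genes with a strict filter, genes below the median level left out (68.4% higher in lines), fewer being tested, 1314 with CI-1040 arms, and 1142 to 2066 on leaving out specimens or replicates.

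With the strict filter, 12 lists passed against the specimens, and 18 to 22 on leaving out specimens or replicates. With an estimated correlation 0 lists passed for CI-1040 and 8 against the specimens, since that test counts correlated genes as less evidence. With fry 19 passed for CI-1040. Leaving out replicates kept that count at 12 in camera.

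As a replicate block, the number gave 5569 genes over lines, a median of 1622 per line and 4675 became 5222 genes differing between lines; the line as a fixed block gave 5652. Same-numbered arrays of both arms correlated above 0.1 throughout in only 7 of 22 lines, so the numbers were not taken as pairs. Yet 36 of 66 vehicle arrays were closest to their own number, against 22 with shuffled numbers (one-sided permutation p = 0.00123, a test added after seeing the data), a hint of shared handling by number.

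The relations stayed unpassed, with moved r. MAPK output with proliferation gave 0.0355 under quantile normalization, 0.0342 with median centring, 0.0468 with 22 lines and 0.158 without the 2 farthest units. Vehicle MAPK output with its change gave -0.134 with a floor of 64, -0.102 with 22 lines and -0.0835 without the 2 farthest. Epithelial minus mesenchymal with MAPK output gave 0.126 with a mild and 0.167 with the strict filter on dim genes, 0.0019 and 0.0463 with floors of 16 and 64, and 0.121 without the 2 farthest. The cause was not tested. Folds of dim genes depended on the intensity floor and were smaller with higher floors, as for NMU, 7.57 at a floor of 1 and 3.96 at 64. About 30.5% of an array's values lay below 50, and thus below the floor of 64.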

Other observations

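All values here were looked at after the main results were seen.

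Lines known to share an origin had similar vehicle profiles. After centring each gene over lines, COLO357 correlated with L3.3 at r = 0.670 across genes, which are not independent replicates, and PL45 with Panc-10.05 at 0.712. Among the lines without a known relative, the highest was 0.378, between Capan-2 and Panc-5.04. The CI-1040 profile of Panc-10.05 was nearly as close to the vehicle profile of PL45 (0.781) as to its own (0.802), whereas that of PL45 had 0.839 with its own and 0.474 with Panc-10.05. A mix of arrays of these lines was not excluded, which would change what the Panc-10.05 values mean.

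The number of changed genes did not follow the fall of MAPK output alone. L3.6pl had 420 changed genes with MAPK output at -1.47, and MPanc-96 had 2190 at -0.84. The replicate SD was 0.174 in L3.6pl and 0.259 in MPanc-96. Since the counts rest on a spread pooled over 47 groups, noisier lines can get more calls, so the counts are no pure measure of response. The change of COLO357 correlated with the mean change of the other lines at r = 0.104 across genes, and that of Panc-2.03, the highest, at 0.833.

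The normal specimens differed among themselves. The acinar list lay at 9.35, 10.85 and 7.92 in specimens 1, 2 and 3, and the G2/M list at 5.72, 7.01 and 7.32. The fibroblast list lay at 8.07, 9.47 and 9.27, and the duct list at 9.24, 9.40 and 9.49.

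Arrays numbered 2 shared a deviation from their group means. On the first component of deviations within groups, which held 16.2% of that variance, replicate 2 was highest in 41 of 47 groups. The 6 exceptions were the CI-1040 groups of COLO357, L3.6pl, L3.6sl and PL45 and specimens 1 and 2. The mean correlation of deviations, across genes, was 0.128 between arrays numbered 2, 0.0592 between those numbered 1 and 0.0425 between those numbered 3. The numbers are balanced over both arms.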
